A study of Arabidopsis thaliana with 9 samples.

How the data were processed

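RNA sequencing was used to measure gene expression in 9 samples of Arabidopsis thaliana seedlings, 9 days old and grown on medium with 2% sucrose. Per the labels the samples form 3 groups of 3 libraries: the tt19 knock-out mutant tt19-8, and the lines OE1 and OE2, which overexpress CsGSTF1. The labels do not say whether libraries of a group come from separate cultures, so every p-value measures only the spread between these samples. CsGSTF1 is a tea gene and is not in the files, so its level was not analysed here.

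The deposited values are in FPKM (fragments per kilobase of gene, relative to library size), 1 file per sample, with 33602 genes in each. The labels name HISAT 0.1.6, edgeR and the build TAIR10, without saying what each was used for. The gene lengths, the totals behind the FPKM and any filter are not stated. Of the gene identifiers, 32835 were matched to the TAIR10.1 annotation, from which symbols and positions were taken. The files themselves hold gene identifiers only. Symbols such as PAP1 follow common usage: PAP1 and PAP2 are the MYB regulators of anthocyanin, and PAP5 and PAP14 are purple acid phosphatases.

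Depth is not given. In OE1 and tt19-8 the low values of 9610 single-exon genes lie on steps such as whole fragment counts give. From these steps the total behind the FPKM was 48.6 M, 50.7 M and 54.8 M fragments in OE1 replicates 1, 2 and 3, and 51.9 M, 48.8 M and 57.5 M in tt19-8. In a gene of 1 kb, 3 counts then correspond to 0.0522 to 0.0618 FPKM, which covers counting error only. In shorter genes the same counts correspond to more FPKM. The OE2 values show no such steps and their depth is unknown.

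Because the values are FPKM, the test was limma 3.58.1 (R 4.3.3), as laid down for that case before the data were examined. Values were taken as log2(FPKM + 1), for the 18232 genes with at least 1 FPKM in at least 3 libraries. The remaining 15370 genes were not tested. All 9 libraries entered 1 fit with a term per group, and eBayes was run with trend and robust on. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05 and no fold minimum. No scaling between samples was applied beyond that in the deposited values. The pseudocount of 1 FPKM shrinks the log2 changes of genes near or below 1 FPKM. Errors of log2 changes are limma standard errors, and errors of FPKM are SD over 3 libraries. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

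The comparisons were OE1 with tt19-8, OE2 with tt19-8, the mean of both lines with tt19-8, OE2 with OE1, and the genes changed the same way in both lines. Tested on simulated data, with 200 of 18232 genes changed, the fit recovered 56% of log2 changes of 1 and 90% of log2 changes of 2 for OE1 against tt19-8, with 3 false among 149 calls. The shares were 59% and 99% for OE2 against tt19-8, with 7 false among 165 calls, and 63% and 93% for OE2 against OE1, with 7 false among 163 calls. The simulated noise was independent between libraries, and changes were placed only in genes above about 5 FPKM. These shares therefore leave out the link between OE1 and OE2 libraries described below, and say nothing of lower genes.

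The genes named were chosen by a rule fixed before the data were examined. It takes TT19, and per pairwise comparison the 8 largest rises and 8 largest falls past the threshold whose libraries do not overlap and whose mean over both groups is at least 5 FPKM. For the genes changed the same way in both lines it takes up to 10 each way under the same conditions. It adds up to 4 members of each gene list with the smallest adjusted p, all members of the lists of early flavonoid genes, anthocyanin late genes and flavonoid regulators, and the reference genes.

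The 25 gene lists were also fixed before the data were examined, from textbook knowledge. They are general phenylpropanoid genes, early flavonoid genes, flavonol glycosylation genes, anthocyanin late genes, proanthocyanidin genes, flavonoid regulators, phi-class and tau-class glutathione S-transferases, vacuolar flavonoid transport, and sulfur and glutathione metabolism. The others are oxidative stress, cold with drought and abscisic acid, salicylic acid defence, jasmonate, photosynthesis, aliphatic and indole glucosinolates, iron, phosphate starvation, the circadian clock, heat shock, sugar starvation and senescence, root markers, seed storage genes and reference genes. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, then with the correlation estimated from the data. It was also tested on its own with fry, and adjusted over the 25 lists. Fry was run on unscaled values and does not compare with other genes, so a shift of all genes can move a list.

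The replicate numbers were checked for pairing through the correlation, across genes, of each library's deviation from its group mean. Same-numbered OE1 and OE2 libraries gave 0.95, 0.96 and 0.96. OE1 and tt19-8 gave -0.06, 0.04 and 0.03, and OE2 and tt19-8 gave -0.03, 0.03 and 0.01. The numbers therefore pair OE1 with OE2, and a fit with the number as a block is given beside that comparison.

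The alternatives set beforehand were a pseudocount of 0.1, no filter, a filter of 5 FPKM, a fold minimum of 1 on the log2 scale, robust off, only the groups compared, a replicate block, organelle genes left out, the 6 transgenic libraries as 1 group, and each library left out in turn. Median-ratio scaling between libraries, and the block fits that hold OE1 and OE2 alone or add this scaling, were added after the data were seen. Alternatives that need read counts (DESeq2 size factors and Wald test, scaling by library totals) were not run, since the values are FPKM.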

Results

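Transcript levels were measured by RNA sequencing in 3 groups of 3 seedling samples. The group tt19-8 is a knock-out of TT19 (AT5G17220, chromosome 5, 5658416 to 5659661, forward strand, TAIR10.1), also called GSTF12, a glutathione S-transferase that anthocyanin needs to accumulate. OE1 and OE2 overexpress CsGSTF1, a tea glutathione S-transferase. By the title of the series, the question is whether CsGSTF1 restores anthocyanin in tt19-8. Pigment was not analysed here, and the comparisons show which transcripts differ.

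TT19 itself stayed below 1 FPKM in every library, and read higher in OE2 than in the other groups. It measured 0.113, 0.0399 and 0 FPKM in tt19-8 replicates 1, 2 and 3, and 0, 0.0769 and 0.0712 FPKM in OE1. In OE2 it measured 0.864, 0.674 and 0.876 FPKM, above every library of the other groups. The low values of OE2 show no count steps, and the cause of this difference was not tested. With less than 1 FPKM in every library, TT19 was below the filter and was not tested.

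The library totals were 1059201 ± 24338 FPKM in OE1, 892212 ± 22818 FPKM in OE2 and 1072113 ± 21035 FPKM in tt19-8 (SD, n = 3). The first principal component held 43% of the variance. Replicates 1 and 2 of tt19-8 lay at 47.1 and 56.6 on it, replicate 3 at 6.2, the OE1 libraries between -15.1 and 3.4, and the OE2 libraries between -34.5 and -20.9. Replicate 3 of tt19-8 also lay nearer to OE1 by spread. Over genes above 50 FPKM, the SD of its log2 ratio was 0.501 and 0.548 to the other tt19-8 libraries and 0.269 to 0.344 to the OE1 libraries. EXT3 (AT1G21310), an extensin of the cell wall, took 5.2% of all FPKM in that library and 2.8% to 6.13% in OE1, where it was the highest gene. The highest gene of tt19-8 replicates 1 and 2 was the aquaporin gene PIP2A (AT3G53420), with 2.29% in each.

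OE2 values were not independent of OE1 values. In the 3 same-numbered pairs, no OE2 value lay below 0.6002 times the OE1 value over 21905 to 22196 genes. None of these genes was at 0 in OE2. In each of the other 69 ordered pairs of libraries, 264 to 2274 genes were at 0 in the first library and above 0 in the second. In all 3 same-numbered pairs 1303 genes lay within 2% of each other, against 5 genes when the numbers were shifted. P-values that involve OE2, and counts that combine both lines, are therefore not evidence from a separate line. Those of OE1 against tt19-8 are also touched, since the shared fit takes its spread from all libraries, OE2 among them. With only OE1 and tt19-8 in the fit no gene was called (lowest limma adjusted p 0.168).

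**Figure D1:**
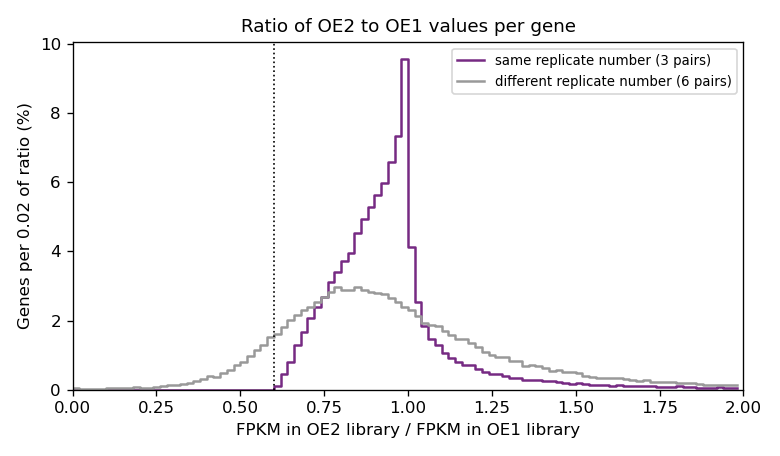
Distribution of the ratio of the FPKM in an OE2 library to that in an OE1 library, over tested genes with at least 1 FPKM in OE1, as percent of genes per 0.02 of ratio. The purple line pools the 3 same-numbered pairs and stops at the dotted line at 0.6, and the grey line pools the 6 pairs with different numbers and extends below it.

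In OE1, no anthocyanin late gene passed the test against tt19-8, and the members went both ways (list median log2 change 0.04). DFR (AT5G42800), which makes leucoanthocyanidins, measured 508 ± 67.2 FPKM in OE1 and 308 ± 40.8 FPKM in tt19-8 (SD, n = 3), with every OE1 library above every tt19-8 library. Its log2 change was 0.72 ± 0.17 (adjusted p = 0.175). LDOX (AT4G22880), the next enzyme, measured 34.9 ± 8.35 and 23.3 ± 3.53 FPKM, with a log2 change of 0.55 ± 0.19 (adjusted p = 0.196). UGT75C1 (AT4G14090), an anthocyanin glucosyltransferase, measured 68.3 ± 12.7 and 47.9 ± 5.79 FPKM, with a log2 change of 0.49 ± 0.18 (adjusted p = 0.2). CHS, the entry enzyme of the flavonoid pathway, measured 1110 ± 90.5 FPKM in OE1, and 2650, 1740 and 867 FPKM in tt19-8 replicates 1, 2 and 3. BGLU10, an anthocyanin glucosyltransferase, measured 42.5 ± 7.39 and 65.5 ± 19.2 FPKM, with a log2 change of -0.58 ± 0.23 (adjusted p = 0.219), and UGT79B1, of the same list, measured 12.9 ± 3.59 and 16.2 ± 5.07 FPKM. The regulator PAP1 measured 6.2 ± 4.04 and 3.09 ± 0.656 FPKM.

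Over all 18232 genes, limma called 3 genes in OE1 against tt19-8, and 3458 genes had an unadjusted p under 0.05. All 3 lay below the level set for named genes and were picked after their values were seen. AT5G59060, a reverse transcriptase family gene, rose from 1.46 ± 0.223 to 4.72 ± 0.124 FPKM. AT1G69710, an RCC1 family gene, fell from 3.87 ± 0.812 to 0.731 ± 0.0718 FPKM, and the chloroplast gene ATCG00620 fell from 2.3 ± 0.337 to 0.171 ± 0.148 FPKM. The log2 changes were 1.22 ± 0.15, -1.48 ± 0.17 and -1.5 ± 0.17, each with an adjusted p of 0.037. The counting limit given above is for a gene of 1 kb, and the counts behind these 3 genes were not worked out. Groups did not overlap for 17.5% of genes, where chance gives 10%. The median log2 change of all genes was -0.109, and after median-ratio scaling 2 genes were called. Without replicate 3 of tt19-8 the count was 3128 genes (782 higher and 2346 lower), DFR passed upward with an adjusted p of 0.0345, and BGLU10 and CHS passed downward with log2 changes of -0.83 and -0.95 (adjusted p = 0.0231 and 0.0176). With any other library left out the count was 0.

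Phosphate starvation genes had lower members in OE1. None of the 11 measured members passed over all genes, and 5 were lower adjusted over the list alone. The phosphate transporter PHT1.1 measured 20.7 ± 3.51 FPKM in OE1 and 47.9 ± 10.5 FPKM in tt19-8, a log2 change of -1.16 ± 0.19 (adjusted p = 0.175). The pyrophosphatase gene PS2 and the transporter gene PHT1.4 had log2 changes of -1.08 ± 0.23 and -0.96 ± 0.26 (adjusted p = 0.175 and 0.178). Seed storage genes had 3 of 5 lower adjusted over the list alone, with library totals of 100.8, 621.2 and 121.7 FPKM in tt19-8 and 16.6, 75.1 and 3.3 FPKM in OE1. In the anthocyanin late genes and in photosynthesis 1 member each was higher adjusted over the list alone, and in jasmonate, iron and root markers 1 each was lower. The other 18 lists had none, and no list had a member past the threshold over all genes. No list passed camera in OE1 against tt19-8 (lowest adjusted p = 0.09, phosphate starvation). With fry the root markers moved down (adjusted p = 0.0322), while camera gave them an adjusted p of 0.324. Camera passed 4, 1, 2, 1, 3 and 1 lists without OE1 replicates 1 and 2, OE2 replicates 2 and 3, and tt19-8 replicates 1 and 2. In early flavonoid genes and jasmonate the median log2 change in OE1 was 0.01 and the mean below 0, in salicylic acid defence and photosynthesis the median was below 0 and the mean above it, and in oxidative stress, iron, the clock and heat shock both were below 0 while camera pointed up.

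In OE2, 3 anthocyanin late genes and 5 flavonoid regulators rose against tt19-8, and 1 regulator fell. LDOX rose from 23.3 ± 3.53 to 52.2 ± 4.78 FPKM (SD, n = 3), a log2 change of 1.14 ± 0.19 (adjusted p = 0.00719). UGT75C1 rose to 76.1 ± 9.86 FPKM, by 0.66 ± 0.18 on the log2 scale (adjusted p = 0.0314), and DFR rose to 475 ± 55.3 FPKM, by 0.63 ± 0.17 (adjusted p = 0.0319). For DFR and UGT75C1 the log2 changes in OE1, given above, were of like size, and p-values were adjusted within each comparison. Their calls in OE2 alone are therefore no difference between the lines. The MYB regulators of anthocyanin PAP1 and PAP2 rose by 1.77 ± 0.35 and 2.04 ± 0.29 on the log2 scale (adjusted p = 0.0111 and 0.00395), to 13.1 ± 3.86 and 7.04 ± 0.497 FPKM. The flavonol regulator MYB111 rose by 1.11 ± 0.2 (adjusted p = 0.00856), and LBD39, a repressor of PAP1 and PAP2, fell by 1.09 (adjusted p = 0.00978). In all, 3 of 9 measured anthocyanin late genes rose and none fell, and the same 3 passed adjusted over the list alone. Without tt19-8 replicate 3, 3 anthocyanin late genes rose and 1 fell, and 1 early flavonoid gene fell. Of 17 measured flavonoid regulators 5 rose and 1 fell, with the same counts adjusted over the list alone. The 5 measured early flavonoid genes did not pass (CHS log2 change -0.6 ± 0.33, adjusted p = 0.218), and F3H was at 0.0236 ± 0.0291 FPKM in OE2 and at or below 0.0262 FPKM in the means of the other groups. DFR, of the same pathway, was at 475 ± 55.3 FPKM in OE2. Whether the low F3H values come from the plants or from how the gene was quantified was not tested.

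**Figure D2:**
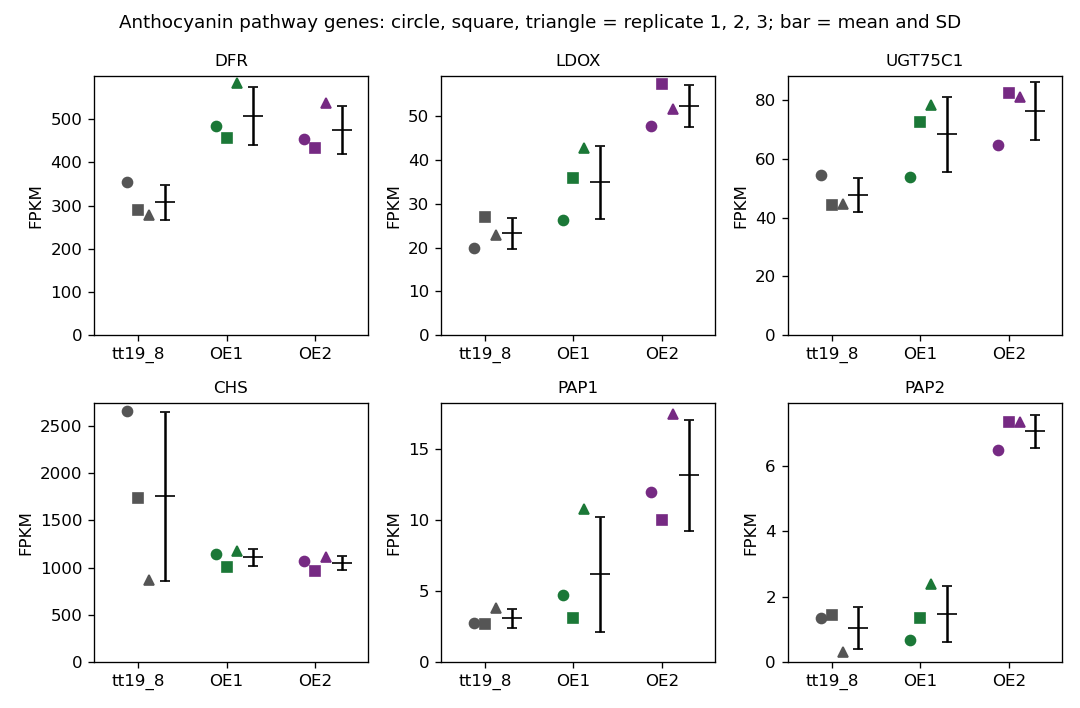
FPKM of 6 flavonoid and anthocyanin genes in each library of tt19-8 (grey), OE1 (green) and OE2 (purple). Circles, squares and triangles are replicates 1, 2 and 3, and black bars are means with SD. For DFR, LDOX, UGT75C1, PAP1 and PAP2 every OE2 library lies above every tt19-8 library, and tt19-8 replicate 3 has the lowest CHS value, 867 FPKM.

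The 8 largest rises of named genes in OE2 fell to genes of several kinds, and AT5G57785, of unknown function, had the largest (3.74 on the log2 scale, adjusted p = 2.83e-05). The metallothionein genes MT1C (AT1G07610) and MT2A (AT3G09390) rose from 2.02 ± 0.651 to 37.3 ± 8.37 FPKM and from 146 ± 38.2 to 1290 ± 347 FPKM, with log2 changes of 3.66 ± 0.24 and 3.12 ± 0.27 (adjusted p = 0.000108 and 0.000405). The dehydrin gene LTI30 rose from 4.21 ± 0.282 to 44.9 ± 13.9 FPKM, by 3.09 ± 0.21 (adjusted p = 0.000108). LSU2, which responds to low sulfur, rose by 3.06 ± 0.29 (adjusted p = 0.000497). The others were the glutathione S-transferase GSTU4 (2.92), the histone gene HIS4 (2.81) and the knottin family gene AT2G43530 (2.73), with adjusted p of 0.00114 to 0.00539. The largest falls were the peroxidase gene AT5G64120, from 257 ± 100 to 72 ± 19 FPKM with a log2 change of -1.78 ± 0.28 (adjusted p = 0.00593), AT5G17340 (-1.76), PAP5 (-1.76), AT5G37210 (-1.72), AT4G31530 (-1.7), AT2G07667 (-1.69), PAP14 (-1.63) and the phospholipase gene PLA2A (-1.62).

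Of 23 measured tau-class glutathione S-transferases 4 rose in OE2 and none fell, and 5 rose adjusted over the list alone. GSTU19 rose from 67.9 ± 5.69 to 190 ± 26.5 FPKM (log2 change 1.46 ± 0.17, adjusted p = 0.00166), and GSTU7 and GSTU5 rose by 1.86 and 1.53 (adjusted p = 0.00186 and 0.0209). In the phi class, the class of TT19, 1 of 11 rose over all genes and over the list alone, GSTF5, by 1.16 ± 0.16 (adjusted p = 0.00359). Of 18 cold, drought and abscisic acid genes 3 rose by both counts: LTI30, COR47 (1.16 ± 0.19, adjusted p = 0.00639) and RD29A (1.42 ± 0.36, adjusted p = 0.0254). In sulfur and glutathione metabolism 2 of 10 rose and 3 fell, against 5 and 3 adjusted over the list alone. LSU2 and the sulfate reduction gene APR2 (1.05 ± 0.16, adjusted p = 0.00518) rose, and the glutathione synthetase gene GSH2 and the sulfate transporter gene SULTR1.2 fell by 0.69 and fell by 0.82.

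Camera passed 3 lists upward in OE2 against tt19-8. They were the tau-class glutathione S-transferases (adjusted p = 2.93e-05), the cold, drought and abscisic acid genes (adjusted p = 0.000173) and the flavonoid regulators (adjusted p = 0.00714). For all 3 the adjusted p was 0.657 with an estimated correlation. Anthocyanin late genes gave an adjusted p of 0.055. Camera passed 6 lists without OE2 replicate 1 and 5 without OE1 replicate 3.

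Among general phenylpropanoid genes 1 of 8 rose in OE2, C4H (0.69 ± 0.2, adjusted p = 0.0359), and 3 fell: PAL3, 4CL1 and 4CL3 (log2 changes -0.81, -0.81 and -0.69). Of 4 vacuolar transport genes 3 fell, ABCC1, ABCC2 and ABCC3 (-0.76, -0.61 and -0.68), and 4 were lower adjusted over the list alone. In oxidative stress 1 of 14 rose, the zinc finger gene ZAT12, and 3 fell, APX1, CAT1 and CAT3 (-1.04, -0.68 and -0.99). In phosphate starvation 3 of 11 rose, with IPS1 and SPX1 at 1.71 and 0.82, and 2 fell, PHT1.1 and PS2 at -1.45 and -0.95. Photosynthesis had 2 of 21 higher, the light-harvesting genes LHCB1.1 and LHCB2.3 (1.23 and 1.34). Indole glucosinolate genes had 3 of 7 lower and aliphatic glucosinolate genes 2 of 11. Root markers had 3 of 11 lower, the root hair genes EXPA7, COBL9 and RSL4 (-0.85, -0.75 and -0.79). With fry the root markers and the indole glucosinolate genes moved down (adjusted p = 0.000473 and 0.0129). Camera, which compares with all other genes, did not pass them (adjusted p = 0.158 and 0.203). The median log2 change of all genes was -0.184, so fry does not tell these lists from that shift. After median-ratio scaling 1 gene was lower in each of the phenylpropanoid, vacuolar transport, indole glucosinolate, phosphate and root lists, 2 in oxidative stress, and none in sulfur metabolism and the aliphatic glucosinolate list.

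In the clock list 1 of 12 rose, ELF4 (1.81), and 3 fell, and in iron 2 of 8 fell, but after median-ratio scaling none was lower in either. In jasmonate 1 of 18 fell (LOX4, -1.05), in salicylic acid defence 1 of 13 rose (PR2, 2.67), and in heat shock 1 of 3 rose (HSP15.7, 1.09). In sugar starvation and senescence 1 of 6 rose (BGLU30, 1.78) and 1 fell (DIN10, -0.8). Of the 6 reference genes TIP41 rose (0.52 ± 0.14, adjusted p = 0.0312) and none fell. Flavonol glycosylation (5 measured), proanthocyanidin (3 measured) and seed storage genes (5 measured) had none past the threshold. Adjusted over the list alone, the counts differed from these in phenylpropanoids (4 lower), oxidative stress (2 higher, 4 lower), phosphate starvation (4 lower), sugar starvation (2 higher) and root markers (5 lower). In flavonol glycosylation, phi-class transferases, oxidative stress, jasmonate, iron, phosphate starvation, the clock and sugar starvation the median log2 change was below 0 while camera, which compares with all other genes, pointed up (adjusted p 0.587 to 0.981), and the median turned positive after median-ratio scaling in flavonol glycosylation, the phi class, jasmonate, iron and the clock. In early flavonoid genes the median was 0.12 and the mean -0.06.

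Over all genes limma called 3467 genes in OE2 against tt19-8, 821 higher and 2646 lower. The libraries of the groups did not overlap for 3443 of them, and for 37.1% of all genes, where chance gives 10%. The median log2 change of all genes was -0.184, and relative to it, after median-ratio scaling, the calls were 2263 (1295 higher and 968 lower). The scaled log2 changes were 1.35 for LDOX, 0.87 for UGT75C1, 0.84 for DFR, 3.83 for MT1C and -1.57 for AT5G64120, all past the threshold, while 19 of 73 named calls were lost, among them 4CL1, ABCC2, ABCC3, GSH2 and AT2G07667. The count was 530, 1499 and 780 without OE2 replicates 1, 2 and 3, and 1274, 1039 and 5967 without tt19-8 replicates 1, 2 and 3, and without any of the OE2 libraries or tt19-8 replicate 2 the calls for DFR and UGT75C1 ended, as did DFR without OE1 replicate 1 and with only OE2 and tt19-8 in the fit (highest adjusted p over the alternatives 0.117), UGT75C1 without tt19-8 replicate 1 and PAP1 without tt19-8 replicate 2. Of the 73 named calls 32 held in every alternative that tested them, among them LDOX, PAP2, MYB111, MT1C, MT2A, LTI30, GSTU4 and GSTU19, and of 71 calls tested 38, 21 and 33 ended without OE2 replicates 1, 2 and 3, and 34 and 36 without tt19-8 replicates 1 and 2. With only the groups compared in the fit 9 of the 73 ended, and without a filter 10.

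The mean of both lines against tt19-8 asks for the average change with the transgene. The fit treats the linked OE1 and OE2 libraries as independent, so the errors and p-values of this comparison tend to be too small. DFR rose by 0.68 ± 0.15 on the log2 scale (adjusted p = 0.0247), LDOX rose by 0.84 ± 0.17 (adjusted p = 0.0211) and UGT75C1 rose by 0.58 ± 0.15 (adjusted p = 0.0389). LHCB2.3 rose by 1.33 ± 0.24 (adjusted p = 0.0186), from 9.32 ± 3 FPKM to 24.8 ± 7.58 FPKM in OE1 and 25 ± 7.19 FPKM in OE2 (SD, n = 3). PHT1.1 and the lipoxygenase gene LOX4 had log2 changes of -1.31 ± 0.16 and -1.03 ± 0.18 (adjusted p = 0.00975 and 0.0185). Of the phosphate starvation list 4 of 11 fell and none rose, also adjusted over the list alone. Of the root markers 3 of 11 fell, and 4 adjusted over the list alone. With fry the root markers and the indole glucosinolate genes moved down for both lines (adjusted p = 0.000866 and 0.013). Camera did not pass them (adjusted p = 0.215 for each). The seed storage genes CRU3 and CRA1 fell, with log2 changes of -3.38 ± 0.91 and -3.21 ± 0.9 (adjusted p = 0.0392 and 0.0435). After median-ratio scaling 2 phosphate starvation genes, 1 root marker and no seed storage gene were lower.

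Over all genes limma called 2520 genes for both lines, 554 higher and 1966 lower. Camera passed the tau-class glutathione S-transferases (adjusted p = 0.00147), the cold, drought and abscisic acid genes (adjusted p = 0.002) and the flavonoid regulators (adjusted p = 0.0292). With an estimated correlation each had an adjusted p of 0.855. Without tt19-8 replicate 3 camera passed 1 list. The median log2 change of all genes was -0.14. The count was 3 without tt19-8 replicate 2 and 4 without replicate 1, with no gene lower in either, and 5787 without replicate 3. It was 70, 1202 and 280 without OE2 replicates 1, 2 and 3, 599 and 1005 without OE1 replicates 1 and 3, and 1595 after median-ratio scaling (924 higher and 671 lower).

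OE2 against OE1 asks whether the lines differ. MT1C rose from 2.32 ± 0.759 FPKM in OE1 to 37.3 ± 8.37 FPKM in OE2 (SD, n = 3), a log2 change of 3.53 ± 0.24 (adjusted p = 0.000174). IPS1, a non-coding RNA induced by phosphate starvation, rose from 2.99 ± 1.71 to 35.3 ± 16.7 FPKM (3.21 ± 0.41, adjusted p = 0.00331). LTI30 rose by 2.92 ± 0.21 (adjusted p = 0.000194), LSU2 rose by 2.79 ± 0.29 (adjusted p = 0.00106), and the salicylic acid marker PR2 rose by 2.72 ± 0.54 (adjusted p = 0.0385). Of 23 tau-class glutathione S-transferases 3 rose, GSTU4, GSTU19 and GSTU7 (2.78, 1.37 and 1.74), and 6 rose adjusted over the list alone. PAP2 and MYB111 rose by 1.76 ± 0.29 and 0.97 ± 0.2 (adjusted p = 0.0156 and 0.0433), while none of the 9 anthocyanin late genes passed (DFR -0.1 ± 0.17, adjusted p = 1). This fit does not use the pairing of same-numbered libraries, so a small change within pairs is not excluded for these 9 genes. SPX1 and SPX3 of the phosphate list, ELF4, BGLU30, LHCB1.1 and ZAT12 also rose (log2 changes 1.34, 1.38, 1.24, 1.94, 1.2 and 1.49).

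**Figure D3:**
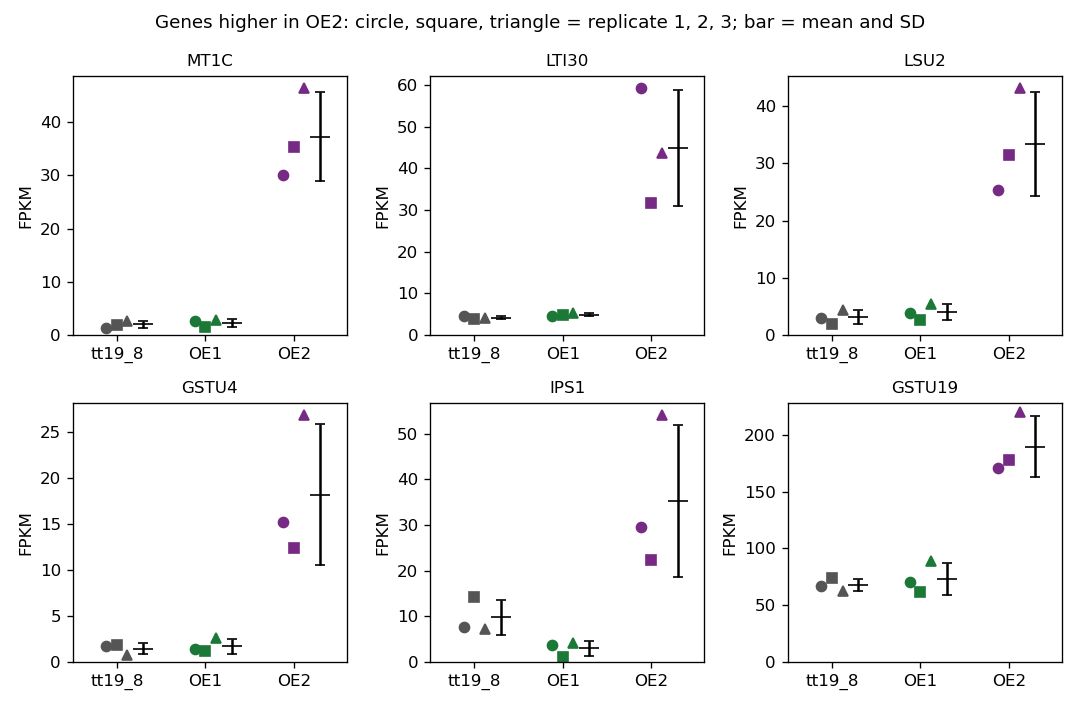
FPKM of 6 genes in each library of tt19-8 (grey), OE1 (green) and OE2 (purple). Circles, squares and triangles are replicates 1, 2 and 3, and black bars are means with SD. In each panel every OE2 library lies above every OE1 and tt19-8 library, with MT1C at a mean of 37.3 FPKM in OE2 and 2.32 FPKM in OE1.

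Over all genes limma called 260 genes in OE2 against OE1, 254 higher and 6 lower, and their libraries did not overlap (21.8% of all genes did not, where chance gives 10%). The 10% holds for exchangeable libraries, and same-numbered OE1 and OE2 libraries are linked. No OE2 value lay below 0.6002 times the same-numbered OE1 value, which limits falls but not rises. The balance of rises and falls is therefore no result about the lines. The 6 lower genes lay near the lower limit of the OE2 to OE1 ratio, among them the RING gene MBR1 (68.9 ± 4.67 to 42.5 ± 2.86 FPKM, log2 change -0.68 ± 0.13, adjusted p = 0.026). Camera passed 7 lists, all upward: the tau-class transferases (adjusted p = 1.17e-06), cold with drought and abscisic acid (0.000176), phosphate starvation (0.00388), flavonoid regulators (0.0048), seed storage (0.0332), heat shock (0.036) and sulfur and glutathione metabolism (0.0459). The limit on falls applies to the members of these lists too. With an estimated correlation each list had an adjusted p of 0.473 to 0.588. Camera passed 4 lists without OE1 replicate 1 or tt19-8 replicate 2. With fry the root markers moved down (adjusted p = 0.037), while camera gave them an adjusted p of 0.221. With the replicate number as a block the count was 334 genes, and with OE1 and OE2 alone in that block, chosen after the data were seen, it was 12031 (2135 higher and 9896 lower), or 12606 after median-ratio scaling (6108 higher and 6498 lower). The count was 55, 65 and 49 without OE2 replicates 1, 2 and 3, 156 and 148 without OE1 replicates 1 and 2, and 467 without tt19-8 replicate 3.

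The calls of OE2 against OE1 for MT1C, AT5G57785, IPS1, LTI30, LSU2, GSTU4, GSTU19, GSTU7 and BGLU30 held in every alternative that tested them. The others named ended in some: SPX3 in 13 of 17, PR2 in 11, MYB111 and ELF4 in 9 each, PAP2 and MBR1 in 6 each, LHCB1.1 in 5, ZAT12 in 4 of 16, and SPX1 and AT2G43530 in 2 each. Of the other lower genes, BIM1, SEC3A, AT5G26850 and EMB2753 ended in 10 of 17 and AT5G51300 in 11, and all 5 ended when any OE1 or OE2 library or tt19-8 replicate 1 was left out, and SEC3A and AT5G51300 also without tt19-8 replicate 2. The replicate block ended the PAP2 call in the fit of all libraries. With OE1 and OE2 alone in that block, chosen after the data were seen, 12031 genes were called and all 260 calls held. That fit is not among the alternatives counted here. The highest adjusted p over the alternatives counted was 0.113 for PAP2, 0.322 for MYB111, 0.168 for SPX3, 0.227 for ELF4 and 0.231 for PR2. Leaving out any OE1 or OE2 library ended the calls for SPX3, MYB111, ELF4 and MBR1, and leaving out OE1 replicate 1 or any OE2 library ended those for PAP2 and LHCB1.1. SPX1 and ZAT12 ended without OE2 replicate 1 or 3, AT2G43530 without OE2 replicate 3, and PR2 without OE1 replicate 1 or 2, OE2 replicate 2 or 3, or any tt19-8 library. Without tt19-8 replicate 1 the calls for SPX3, MYB111 and ELF4 ended, and without replicate 2 or 3 that for SPX3.

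The genes changed the same way in both lines were the 3 called in OE1. AT5G59060 rose in OE2 as well, to 3.19 ± 0.0932 FPKM (SD, n = 3; log2 change 0.77 ± 0.15, adjusted p = 0.0101). AT1G69710 and ATCG00620 fell in OE2 to 0.703 ± 0.0687 and 0.349 ± 0.143 FPKM (log2 changes -1.5 ± 0.17 and -1.29 ± 0.17, adjusted p = 0.00132 and 0.00315). No gene was called in opposite directions, and independent lists of these sizes would share 0.045 genes upward and 0.29 downward. Across genes, which are not independent replicates, the log2 changes of the lines correlated at r = 0.779 with a covariance of 0.14, and 84.4% had the same sign. Simulated unchanged lines that share the 3 tt19-8 libraries gave a mean r of 0.501 (0.482 to 0.517), a covariance of 0.0323 and 66.7% of the same sign. The simulation leaves out the link between same-numbered OE1 and OE2 libraries, so it is no bound for unchanged lines that are linked. The 3 controls could not be divided between the lines, so the part of this overlap that comes from the shared tt19-8 libraries was not separated, and OE2 was not independent of OE1. The count was 2833 without tt19-8 replicate 3 and 0 without any other library.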

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

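The tests of separate samples, other quantification, a fixed share, depth, FPKM totals and splits that keep linked pairs were chosen only after the results were seen, while the wrong-label test and the counts of other splits were set before theirs were. All results here were picked out because OE2 and OE1 carry the same transgene and differed in a direct test. The number of genes that differed was 260, 1 of the 10 splits of those 6 libraries gave as many, and the highest of the other splits gave 0. The largest log2 changes of OE2 against OE1 were 3.53 for MT1C, 3.45 for AT5G57785, 3.21 for IPS1, 2.92 for LTI30, 2.79 for LSU2, 2.78 for GSTU4, 2.72 for PR2 and 2.72 for AT2G43530. The falls were -0.68 for MBR1, -0.68 for BIM1, -0.66 for SEC3A, -0.6 for AT5G26850, -0.6 for AT5G51300 and -0.57 for EMB2753. The MBR1 call ended in 6 of 17 alternatives and the other 5 in 10 or 11, and all 6 ended when any OE1 or OE2 library was left out. The adjusted p of the lists was 0.0048 for flavonoid regulators, 1.17e-06 for tau-class glutathione S-transferases, 0.0459 for sulfur and glutathione metabolism, 0.000176 for cold, drought and abscisic acid genes, 0.00388 for phosphate starvation, 0.036 for heat shock and 0.0332 for seed storage genes. With an estimated correlation none of these lists passed.

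The first pattern is that OE2 values follow the same-numbered OE1 values. Separate plant samples would leave some genes at 0 in OE2, as in each other pair of libraries, and the lowest ratio of 0.6002 over 21905 to 22196 genes argues against them. The same reads quantified by another method remains open for genes with a mean ratio from 0.6 to 1.0, where the slope of log2 OE2 on log2 OE1 within genes was at least 0.89, while slopes of 0.75 (0.74 to 0.76), 0.476 (0.461 to 0.49) and 0.298 (0.255 to 0.339) for ratios from 1.0 to 1.3, 1.3 to 2.0 and 2 to 5 argue against it there. A fixed share of 0.6 of OE1 plus an unrelated library would give a linear slope near 0.6. Slopes of 0.786 (0.782 to 0.789), 0.913 (0.91 to 0.915) and 0.853 (0.844 to 0.862) for ratios from 0.8 to 0.9, 0.9 to 1.0 and 1.0 to 1.3 argue against it there. Slopes of 0.633 (0.63 to 0.637) and 0.689 (0.684 to 0.693) for ratios from 0.6 to 0.7 and 0.7 to 0.8 cannot decide. These classes were set by the same ratios and lie next to their lower limit. A gene's ratios in them can vary little, which holds the linear slope near the ratio and the log2 slope near 1 under either explanation. Slopes of 0.708 (0.678 to 0.749) and 0.679 (0.575 to 0.741) for ratios from 1.3 to 2.0 and 2 to 5 leave the fixed share open. A difference between the lines stays open for genes such as MT1C and LTI30, and was not tested apart from how the OE2 values came about.

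The second pattern is that tt19-8 replicate 3 lies with OE1. A wrong label on that library may account for it: 69 genes set tt19-8 replicates 1, 2 and 3 apart from OE1 by over 0.5 on the log2 scale, and 28, 200 and 76 genes did so when OE1 replicate 1, 2 or 3 took its place. Sequencing depth would bring libraries of like depth together, and the spread of 0.626 between OE1 replicate 1 and tt19-8 replicate 2, with 48.6 M and 48.8 M fragments, argues against it. A tt19-8 sample in another state of growth stays open and was not tested.

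The last pattern is that more genes were lower than higher in OE2 against tt19-8. The share of higher genes was 23.7% of calls, and 57.2% after median-ratio scaling. That scaling sets the median change to 0 and evens the calls whatever the cause, so it decides nothing. In OE1, with totals near those of tt19-8, the median log2 change of all genes was -0.109, against -0.184 in OE2. Without tt19-8 replicate 2 these were -0.053 and -0.135. The lower FPKM totals of OE2, how its values came about and a biological change in many transcripts cannot be told apart.

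Other splits of the libraries were run for the other counts. For OE1 against tt19-8 the real count was 3 and the highest other 0, with 1 of 10 splits as large, and for OE2 against tt19-8 it was 3467 and the highest other 0, with 1 of 10. Like that of OE2 against OE1, these splits are too few for a share under 0.05. For both lines as 1 group of 6 the real count was 1638, 1 of 84 splits was as large, and the highest other gave 662 genes and set the OE2 libraries against the rest. The next gave 611 genes and put OE1 replicate 2 in the place of tt19-8 replicate 3. These splits treat linked OE1 and OE2 libraries as exchangeable. In 10 splits no same-numbered pair was parted, the highest other of these gave 5 genes, and 10 are too few for a share under 0.05. For the genes changed the same way the real count was 3 and 2 of 100 splits gave as many. With linked lines this does not exclude chance, since 1 of the 100, the real one, parted every pair between the lines. The other of the 2 splits took the OE2 libraries as control group and gave 285 genes, and the reason was not tested.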

How the results depend on the processing

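Median-ratio scaling and the block fits on OE1 and OE2 alone or with this scaling were chosen after the data were seen, and the rest was planned. No call named for OE1 against tt19-8, OE2 against tt19-8 or OE2 against OE1 reversed its direction under single changes of the processing (calls for both lines were not followed), but the balance of counts turned: OE2 against tt19-8 went from 821 higher and 2646 lower to 1295 and 968 with scaling, both lines from 554 and 1966 to 924 and 671, and OE2 against OE1 from 254 and 6 to 2135 and 9896 with these lines alone in a block, which became 6108 and 6498 when scaled. The cause was not tested unless stated. The 3 genes of OE1 against tt19-8 became 0 with a pseudocount of 0.1, with a filter of 5 FPKM (which removes all 3), with only the groups compared (lowest adjusted p 0.168, 2515 genes at an unadjusted p under 0.05) and without organelle genes, 16 with a replicate block, and 0 to 3128 with 1 library left out. The 3467 genes of OE2 against tt19-8 became 698 with a fold minimum, 2263 with scaling and 530 to 5967 with 1 library left out. The 2520 genes of both lines became 258 with a fold minimum, 4252 with a block, 1595 with scaling, 1638 with the 6 transgenic libraries as 1 group and 3 to 5787 with 1 library left out. The 260 genes of OE2 against OE1 became 146 with a pseudocount of 0.1, 535 without a filter, 88 with a filter of 5 FPKM, 412 with scaling, 593 with scaling and a block, 12031 with OE1 and OE2 alone in a block, 12606 when that was scaled and 49 to 467 with 1 library left out. The 3 genes changed the same way became 0 with a pseudocount of 0.1, a filter of 5 FPKM, only the groups compared or no organelle genes, 16 with a block and 0 to 2833 with 1 library left out. With an estimated correlation 0 lists passed in any comparison. In OE1 against tt19-8 the lists past the threshold went from 0 to 1 with a block, 2 with scaling and 0 to 4 with 1 library left out. They went from 3 to between 3 and 6 for OE2 against tt19-8 and to between 1 and 4 for both lines with 1 library left out, and from 7 to 4 with scaling and 4 to 9 with 1 library left out for OE2 against OE1. A block with scaling, which was planned for no comparison with tt19-8, gave 466 genes for OE1 against tt19-8 and 448 genes changed the same way. With only the groups compared in that fit these became 1 and 1, or 15 and 14 without scaling. The replicate numbers pair OE1 with OE2 but not with tt19-8. A block in the fit of all libraries takes out spread that only OE1 and OE2 share. Its counts for comparisons with tt19-8, and for genes changed the same way, can therefore be too high. The other planned settings stayed within 1.5 times the count. Of the named calls, 32 of 73 in OE2 against tt19-8, 9 of 24 in OE2 against OE1 and 0 of 3 in OE1 against tt19-8 held in every alternative that tested them. Settings that need read counts were not run, since the values are FPKM. The unknown depth of OE2 leaves its low values without a counting limit.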

Other observations

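The values per library of some transcripts are given here without a further test. PR1, a marker of salicylic acid defence, measured 28.4 FPKM in OE1 replicate 3 and 30.1 FPKM in OE2 replicate 3, and 0.0761 to 5.39 FPKM in the other 7 libraries. Seed storage transcripts totalled 621.2 FPKM in tt19-8 replicate 2, 75.1 FPKM in OE1 replicate 2 and 3.3 FPKM in OE1 replicate 3. In OE2 they totalled 26, 78.3 and 24.3 FPKM in replicates 1, 2 and 3. EXT3 took 3.88%, 6.13% and 2.8% of all FPKM in OE1 replicates 1, 2 and 3, and 3.02%, 4.76% and 2.19% in OE2.

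Single genes named in the lists did not pass in OE1 against tt19-8, and stand for no group. AOC2, an enzyme of jasmonate synthesis, measured 492 ± 73.7 FPKM in OE1 and 323 ± 86.4 FPKM in tt19-8 (SD, n = 3; log2 change 0.63 ± 0.21, limma adjusted p = 0.189), while LOX4, a lipoxygenase of the same list, measured 6.83 ± 0.43 and 15.2 ± 4.59 FPKM (-1.01 ± 0.21, limma adjusted p = 0.175). The iron transporter gene OPT3 measured 52.6 ± 2.02 and 84.7 ± 19.1 FPKM (-0.65 ± 0.17, limma adjusted p = 0.178), and LSU1, which responds to low sulfur, measured 14.1 ± 2.26 and 8.23 ± 4.41 FPKM (0.81 ± 0.29, limma adjusted p = 0.198). The cold genes COR15B and KIN2 measured 147 ± 51.2 and 690 ± 185 FPKM in OE1, and 75 ± 4.77 and 395 ± 86.5 FPKM in tt19-8 (limma adjusted p = 0.188 and 0.192).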
